A study of Mus musculus with 2 samples.

How the data were processed

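Single-cell ATAC-seq was deposited for 2 libraries of mouse 3xCr high-grade glioma, 1 per diet. Per the labels' protocols, tumour tissue was collected by GFP expression and dissociated, nuclei were tagged with Tn5 transposase, and libraries were made with a 10x Genomics droplet kit. Nuclei were not sorted, so shares of cell types also depend on how each tumour was dissected. The meaning of the name 3xCr is not given in the sources used here.

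Each library was deposited as a list of fragments with their chromosome, start, end, barcode and a count. Per the file headers, this count is the number of read pairs of a unique fragment, made with Cell Ranger ATAC 2.1.0 on a reference of mm10 with an added GFP contig, built with Cell Ranger ARC 2.0.2. The submitters' processing notes also name Seurat 5.1.0 and Signac 1.14.0, without saying for what they were used. Fragment ends were used as deposited, with no further shift for the Tn5 overhang. All barcodes were used as deposited, and the calling of nuclei was done anew. Each fragment was counted as 1, whatever its read pairs. The control library held 101793672 read pairs and the restricted library 75726505.

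Gene names and positions came from a RefSeq table of GRCm38.p6, the assembly also called mm10, which gives no strand. Of its 49997 genes, the 21883 protein-coding ones with a unique symbol on chromosomes 1 to 19, X and Y were used. Without strand, 2 steps differ from the plan. The window of a gene was its body with 2 kb on either side, in place of 2 kb upstream only, and a fragment counted where it overlapped the window. The promoter was taken as the end of the gene that had more fragment ends within 1 kb in barcodes too shallow for analysis, from both libraries with equal weight. For 11925 genes (54.5%) 1 end clearly had more, and the TSS enrichment rests on 9102 of them that lie apart from others. Promoter values of the remaining genes are less certain.

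Nuclei were barcodes with 2000 to 100000 nuclear fragments, a TSS enrichment of at least 5 and a nucleosome signal, the ratio of mononucleosomal to shorter fragments, under 4. Doublets were scored by their share of simulated doublets among 50 neighbours, with 2 simulated per nucleus, and 0.8% of nuclei per 1000 nuclei were removed, 135 of 4103 (3.29%) in control and 18 of 1490 (1.21%) under restriction. The 3968 and 1472 nuclei kept were clustered together on 215023 autosomal tiles of 5 kb that were open in at least 0.5% of nuclei, by TF-IDF, 30 singular value components and Leiden clustering at resolution 1 on 20 neighbours. Component 1 followed depth (correlation 0.965) and was dropped. No correction between the libraries was made.

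Of 23 clusters, 17 were named from marker lists fixed before the data were examined. The thresholds of naming were set after the data were seen. A cluster took the class with the highest mean z score of its markers if that was at least 0.8, was 0.1 above related classes, rested on at least 3 markers, and no other lineage reached 0.8. Neurons, astrocytes, oligodendrocytes, their precursors and neural progenitors count as related classes of 1 lineage. It stayed unnamed where its 10 leading genes by fold held more markers of another class than of its own. Leading genes needed a mean activity of 20 fragments per 1000000. Minimums of 10, 30 and 50 were also tried, and 2 clusters, 11 and 14, lost their name at 10 and none at 30 or 50. Glial-lineage nuclei are the astrocyte-like, oligodendrocyte precursor-like and neural progenitor or glioma-like clusters together, because nothing in the labels marks tumour nuclei.

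Gene activity was the sum of fragments over nuclei of a class and library, scaled to the sum over all genes. Log2 ratios are restricted over control with a prior count of 0.5, and their intervals are exact binomial intervals of the restricted share of the 2 counts. Shares of nuclei and fragments have exact Clopper-Pearson binomial intervals. All intervals are at 95% and cover counting error only. With 1 library per group, no test, p-value or number of changed genes is given. Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

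The named genes had a mean activity of at least 20 per 1000000, an interval of the log2 ratio that excluded 0 and a promoter ratio of the same sign. Of these, the 10 highest and 10 lowest ratios are named in glial-lineage nuclei, and the 5 highest and 5 lowest in myeloid-like nuclei. Of each list, the 2 members with the largest absolute ratio at that minimum are named. The results of 4 genes are not reported here, and the counts of values under alternatives leave them out. The rule also counted list members by their interval, and counts of members above and below 0 are given in its place, since intervals from nuclei of 1 library do not show a change. Named regions are the 5 highest and 5 lowest ratios among those with a mean of at least 100 fragment ends at equal totals. Trp53 and the stretches of chromosomes 2, 11, 12, 17 and 18 set out by their copy ratios were chosen after their values were seen, as were oligodendrocyte-like and endothelial-like nuclei, in which the 5 highest and 5 lowest genes are named.

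The 19 lists cover methionine cycle and polyamines, folate and serine one-carbon metabolism, amino acid transport, the ATF4 stress response, methyltransferases, demethylases, cell cycle, hypoxia and glycolysis, interferon response, antigen presentation, mesenchymal and neural progenitor glioma states, astrocyte maturation, oligodendrocyte differentiation, synapse, AP-1, receptor tyrosine kinases and tumour suppressors, and microglia activation and homeostasis. Of 497 list and marker entries, 494 were found in the gene table. The median of a list was placed among 10000 random lists of the same size, drawn from genes within 50 ranks of mean activity. This percentile describes these libraries and is not a test of the diet. The random lists took no account of position, so a list whose members lie side by side can shift together and reach an extreme percentile.

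Accessible regions were called in glial-lineage nuclei, with both libraries thinned to the same total. They were runs of 500 bp tiles with at least 4 times the mean of fragment ends over the surrounding 10 kb and a Poisson tail under 1e-05. Fragments of other classes that lie outside them can therefore still include open chromatin of those classes. Chromosome shares were taken in windows of 10 Mb with at least 1000 myeloid-like fragments per library. For single clusters, fragments outside accessible regions were set against the control library's clusters 2 and 4, and the most likely single step was found in bins of 50 kb, a step of analysis added after the windows were seen.

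On data simulated from the glial-lineage counts over 13048 genes, 95.3% of unchanged genes had an interval that held 0, and 99% of genes changed 1.5-fold lay on the right side of 0. In the myeloid-like simulation over 12585 genes these were 95.6% and 60%, with 92% at 2-fold. Of 100 unshifted lists, 94% and 96% lay inside the central range, and 100% of lists shifted by 0.4 lay above it. Simulated steps were found at a median distance of 0 Mb, on counts of all fragments and not only those outside accessible regions. All simulated counts were independent Poisson draws, the model behind the intervals, without spread between nuclei or animals. They check the computation and do not show how intervals or lists behave in replicate libraries.

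Alternatives covered the gene window, scaling, fragment minimum, depth, activity minimum, neighbouring genes, cluster weights, clustering resolution, doublets and region threshold. Motifs in accessible regions were not analysed here. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.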

Results

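Chromatin accessibility was measured by single-cell ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA and a droplet barcode marks the fragments of each nucleus. The nuclei came from cortical high-grade gliomas of a mouse model called 3xCr, collected by their GFP expression. The mice received a control diet or a diet restricted in methionine from postnatal day 21, and the tumours were taken on postnatal day 50. Methionine is an essential amino acid and the precursor of S-adenosylmethionine, the methyl donor of DNA and histone methyltransferases. There was 1 library per diet. Every difference given here is therefore a difference between these libraries, without a replicate check or a test between the diets, and every interval is a 95% interval that covers counting error only.

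The control library held 48308473 unique fragments from 256001 barcodes and the restricted library 32399074 fragments from 190154 barcodes. Of their read pairs, 52.5% and 57.2% were duplicates of another pair. The nuclei kept numbered 3968 in the control library, with a median of 4073.5 fragments, and 1472 in the restricted library, with a median of 3847. Their median enrichment of fragment ends at transcription start sites (TSS) was 16.3 and 18.5. Over all barcodes, 3 and 6 fragments lay on the GFP contig, so GFP did not mark tumour nuclei in these data.

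The first comparison asks which cell types made up the dissected tissue under each diet. Microglia or macrophage-like nuclei, the resident and infiltrating myeloid cells, were a smaller share of the restricted library, 13.7% (12.005 to 15.587; 202 nuclei) against 27.2% (25.8 to 28.6; 1080 nuclei) in control. Lymphocyte-like nuclei, with the T cell genes Ctla4 and Cd28 among their leading genes, made up 0.951% (0.521 to 1.59; 14 nuclei) against 6.73% (5.97 to 7.55; 267 nuclei). Endothelial-like nuclei, the lining of blood vessels, were a larger share under restriction, at 14.3% (12.5 to 16.2) against 7.86% (7.04 to 8.74). Oligodendrocyte-like nuclei, the myelinating glia, made up 12.2% (10.597 to 14.012) and 10.1% (9.137 to 11.033), with intervals that overlap.

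Among the glial-lineage classes, in which tumour nuclei were expected to lie, the libraries shared few clusters. Oligodendrocyte precursor-like nuclei made up 31.5% (30.1 to 33.0) of the control library, mostly clusters 2, 4 and 16, and 22.2% (20.1 to 24.4) of the restricted library, mostly cluster 5. Astrocyte-like nuclei were 3.55% (3.00 to 4.18) in control, mostly cluster 17, and 12.8% (11.2 to 14.7) under restriction, mostly cluster 11. Neural progenitor or glioma-like nuclei, all in cluster 14, were 0.176% (0.0710 to 0.363) and 10.7% (9.20 to 12.4). No cluster took that name at resolution 0.5 or 2, with nuclei of 1000 fragments let in, with nuclei thinned to equal depth, or with leading genes down to 10 fragments per 1000000. The mean z score of its markers in cluster 14 was 1.35, close to the 1.24 of inhibitory neuron markers. Pericyte or fibroblast-like nuclei made up 1.94% and 2.31%, and excitatory neuron-like nuclei 0.907% and 0.272%. No cluster was named inhibitory neuron-like or ependymal-like. The 6 unnamed clusters held 10.1% and 10.5% of nuclei.

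The myeloid-like nuclei too came mostly from clusters 1, 12 and 13 in control and cluster 9 under restriction, and the endothelial-like nuclei from clusters 6 and 10. With 1 library per diet, a cluster filled mostly by 1 library may be a feature of that library and not of a cell type. The thresholds that name a cluster were set after the data were seen, and the glial-lineage shares rest on them. The 3 glial-lineage classes together were 45.8% under restriction and 35.2% in control, a difference of 10.6 points. It was −11.7 points when genes down to 10 fragments per 1000000 were counted as leading genes, which leaves clusters 11 and 14 unnamed, and −0.438 points with nuclei thinned to equal depth. The astrocyte-like difference of 9.29 points became −2.38 points with the lower minimum, and the oligodendrocyte precursor-like difference of −9.29 points became 10.02 points when nuclei of 1000 fragments were let in. The lower myeloid-like share ranged from −14.9 to −11.8 points over all alternatives, the lower lymphocyte-like share from −8.69 to −4.21 and the higher endothelial-like share from 5.76 to 6.48.

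**Figure D1:**
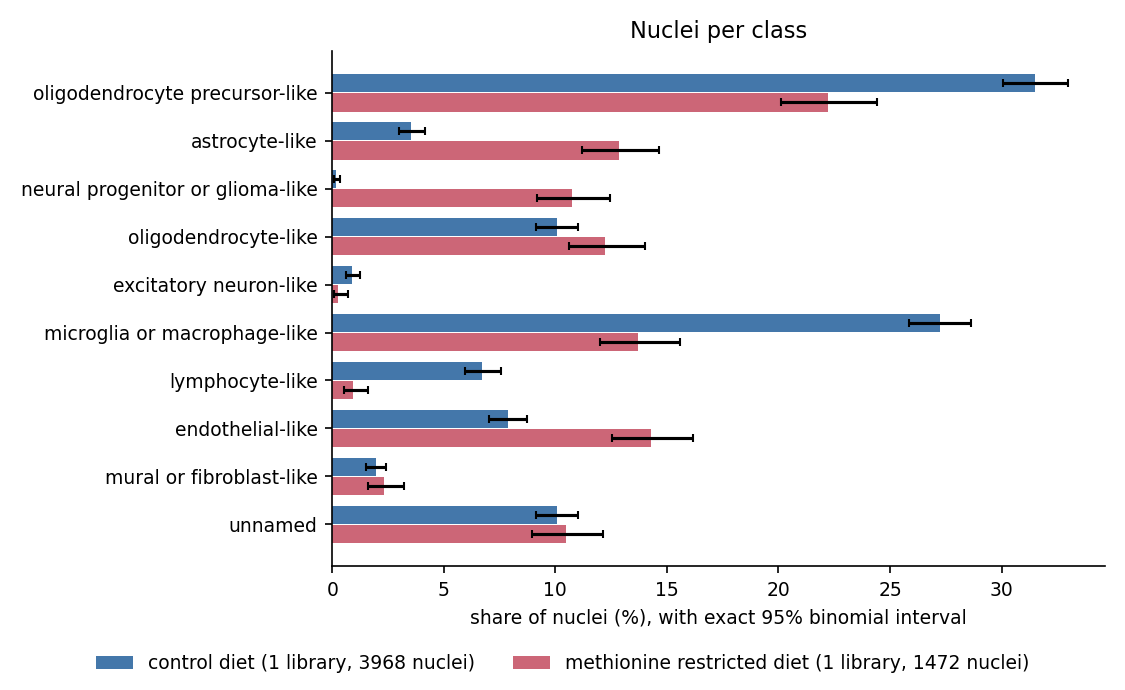
Share of nuclei (% of the nuclei of each library) in each named class and in unnamed clusters, for the control library (3968 nuclei) and the methionine restricted library (1472 nuclei); bars start at 0 and lines are exact 95% binomial intervals, which cover counting error only. Myeloid-like nuclei were at 27.2% and 13.7%, lymphocyte-like nuclei at 6.73% and 0.951%, and endothelial-like nuclei at 7.86% and 14.3%.

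Gene activity, the fragments over a gene and its flanks relative to those over all genes, was then compared in the glial-lineage nuclei. These numbered 1398 in control and 674 under restriction. They were not shown to be tumour nuclei, may include other glia, and leave out the unnamed clusters. The ratios are therefore not shown to be differences between tumour cells. Of the transcription factor genes among those with the highest ratios of restricted over control, Zic1 (chromosome 9, 91358058 to 91365768) had a log2 ratio of 2.24 (1.75 to 2.75), Zic2 2.01 (1.64 to 2.40), Zic4 1.97 (1.60 to 2.35) and Sox1 2.06 (1.72 to 2.42). Genes with the lowest ratios included Lypla2, a thioesterase that removes palmitate from proteins, at −1.73 (−2.08 to −1.40), and Syt4, a synaptotagmin of vesicle traffic, at −1.62 (−2.14 to −1.16). S100a10, the partner of annexin A2 at the plasma membrane, was at −1.58 (−2.08 to −1.14).

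The other genes with the highest ratios were Tmem47, a membrane protein of cell junctions (2.56, 2.03 to 3.13), Ajap1, an adherens junction protein (2.16, 1.77 to 2.56), Lims2, an adaptor of integrin adhesions (2.37, 2.25 to 2.49), and Gpr17, a receptor of committed oligodendrocyte precursors (2.03, 1.87 to 2.20). Lims2 and Gpr17 overlap on chromosome 18, in a stretch whose fragments outside accessible regions were also denser in the restricted library's cluster 5. Cwc22, a splicing factor (2.11, 1.999 to 2.226), and Dnah8, an axonemal dynein (2.01, 1.87 to 2.16), lie in stretches that were higher in all 4 large classes of nuclei, myeloid-like and endothelial-like ones included. The other genes with the lowest ratios were Chmp4c, of the membrane-severing ESCRT-III complex (−1.45), the tetraspanin Cd151 (−1.44), Ahnak2 (−1.39), Kcnmb3, a subunit of calcium-activated potassium channels (−1.39), Pithd1 (−1.36), the cytidine deaminase Cda (−1.31) and Cdsn (−1.29). Lypla2, Pithd1 and Cda lie near each other on chromosome 4 (135968224 to 138368311), and the windows of Lypla2 and Pithd1 overlap. Outside accessible regions, all of chromosome 4 was at 0.661 (0.654 to 0.668) in the restricted library's cluster 14, relative to the control library's clusters 2 and 4. In its cluster 5 it was at 0.999. Minus neighbouring genes, the ratios of Lypla2, Pithd1 and Cda were −1.56, −1.19 and −1.14.

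Several of these genes also lead the clusters that separate the libraries, so their ratios partly restate the clustering. They are Lims2, Gpr17 and Dnah8 in cluster 5, Zic4 in cluster 14, and Kcnmb3 and S100a10 in cluster 16. When the clusters with enough nuclei in both libraries, 5 and 11, were given equal weight, Zic1 (−0.99), Zic4 (−1.24) and Sox1 (−0.26) went the other way, as did Cdsn (0.30).

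Of the 19 gene lists, 4 had a median log2 ratio outside the central 95% of 10000 random lists of the same size and mean activity, where chance gives 0.95. Antigen presentation genes, which load and display peptides to T cells, had a median of −0.32 (percentile 0), with 0 of 14 members above 0. Members that lie side by side may have shifted together, for which the random lists make no allowance. Cd74, the invariant chain of class II molecules, was at −1.25 (−1.66 to −0.88) and H2-D1, a class I heavy chain, at −0.82 (−1.05 to −0.60). Genes of the mesenchymal glioma state, an injury-like program of adhesion and cytoskeletal genes, had a median of −0.52 (percentile 0), with 16 of 18 measured members below 0. S100a10 led them, and Il1rap, a co-receptor for interleukin 1, was at −1.11 (−1.29 to −0.94). Microglia activation genes had a median of −0.29 (percentile 0.260), with 13 of 18 members below 0. Its members with the largest ratios at the activity minimum were Apoe, a lipid carrier, at 0.40 (−0.01 to 0.79), and Hif1a, an oxygen-responsive factor, at −0.20 (−0.46 to 0.06). The median thus comes from members below that minimum, with few fragments, and the intervals of 16 of the 18 hold 0. Markers of another cell type went with these lists. In the same glial-lineage nuclei the summed fragments over 14 macrophage markers, a comparison chosen after the lists were seen, had a ratio of 0.880 (0.811 to 0.954), and of 0.714 (0.610 to 0.832) with nuclei thinned to equal depth, against 0.785 (0.748 to 0.823) and 0.757 (0.695 to 0.824) for the antigen presentation genes. Lymphocyte markers were at 0.964 (0.899 to 1.03). Myeloid-like nuclei of the control library held similar amounts of both, 1525 antigen presentation and 1580 macrophage marker fragments per 1000000. In glial-lineage nuclei antigen presentation genes were at 924 in control and 725 under restriction, but macrophage markers at 298 and 262. With thinned nuclei these were 953 and 721, and 302 and 216. This argues against fewer stray myeloid fragments as the whole reason for the lower antigen presentation genes. Such fragments stay open as a part of it, and as a reason for the lower microglia activation list. They were not weighed for the mesenchymal list, which was lower in all 4 large classes of nuclei. Its median was −0.20 in myeloid-like, −0.26 in oligodendrocyte-like and −0.36 in endothelial-like nuclei, so the lower median was not particular to glial-lineage nuclei.

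Astrocyte maturation genes had the highest median, 0.39 (percentile 100), with 16 of 19 members above 0. The water channel Aqp4 was at 0.95 (0.51 to 1.38) and the gliogenic factor Sox9 at 0.89 (0.61 to 1.17). The high median came from clusters 11 and 14, since it was −0.02 without them and 0.03 in the oligodendrocyte precursor-like clusters alone, where Aqp4 went the other way, at −0.45 and −0.44. In those clusters the mesenchymal median was −0.72 and the antigen presentation median −0.18, at percentile 4.61. With equal weights of clusters 5 and 11, these medians were −0.25 and −0.26, and 1 list in place of 4 lay outside the central range. The microglia activation list lay inside it at promoters alone, at −0.30, and with nuclei thinned to equal depth, at −0.17.

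The lists that bear most directly on methionine lay inside the central range. Genes of the methionine cycle and polyamine synthesis had a median of 0.17 (percentile 94.8), with 15 of 20 members above 0. Adi1, a methionine salvage dioxygenase, was at 1.05 (0.66 to 1.43), and Mat2b, the regulatory subunit of methionine adenosyltransferase, at 0.73 (0.45 to 1.01). Adi1 lies in a stretch of chromosome 12 that was also denser outside accessible regions in cluster 5, and its ratio minus that of neighbouring genes was 0.65. The median of the whole list was 0.03 in the oligodendrocyte precursor-like clusters alone. Folate and serine one-carbon genes had a median of 0.07 (percentile 63.0), with the formyltetrahydrofolate dehydrogenases Aldh1l1 (−0.54) and Aldh1l2 (−0.51) lower. Amino acid transport genes were at 0.05 (percentile 61.6), with Slc43a2, a transporter of large neutral amino acids, at −0.61 and Slc7a11, the cystine importer, at 0.53. Genes of the ATF4 and integrated stress response, which amino acid shortage activates, were at 0.04 (percentile 43.9), with the glutathione-degrading enzyme Chac1 at 0.50 and the lipoprotein receptor Vldlr at 0.46. Histone and DNA methyltransferases were at −0.03 (percentile 27.0), with Dnmt3b (0.58) and Dnmt1 (−0.42) on opposite sides. Demethylases were at −0.07 (percentile 9.51), with 11 of 16 members below 0, among them Kdm1a (−0.42) and Tet3 (−0.40).

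Proliferation, oxygen and interferon genes showed no list outside that range either. Cell cycle genes had a median of 0.13 (percentile 91.1), led by the ribonucleotide reductase subunit Rrm2 (0.78) and cyclin A2, Ccna2 (0.38). Hypoxia and glycolysis genes were at 0.01 (percentile 38.2), with the mitophagy receptor Bnip3 at 0.51 and the glucose transporter Slc2a3 at −0.38. Interferon response genes were at 0.04 (percentile 46.5), with the antiviral enzyme Rsad2, in the denser stretch of chromosome 12, at 0.51.

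The neural lists were also inside the range. Neural progenitor glioma state genes had a median of 0.15 (percentile 87.2), although the neuronal tubulin Tubb3 (−0.90) and Igfbpl1 (−0.64) were lower. Oligodendrocyte differentiation genes were at −0.05 (percentile 22.6), with Gpr17 at 2.03 and the myelin gene Mbp at −0.69. Synapse and glutamate signalling genes were at 0.01 (percentile 68.3), with the receptor subunit Grin2a at 1.22 and the scaffold Dlg4 at −0.48. Immediate early AP-1 genes were at 0.02 (percentile 61.9), with Nr4a2 at 0.66 and Atf3 at −0.35. Microglia homeostasis genes were at −0.09 (percentile 14.4), with Slc2a5 at −0.51 and Olfml3 at −0.47. Receptor tyrosine kinases and tumour suppressors were at 0.08 (percentile 86.2). Among them the growth factor receptor Egfr, a leading gene of cluster 14, was at 1.36 (1.18 to 1.54) and 0.06 with equal cluster weights, and the Ras regulator Nf1 was at −0.53 (−0.66 to −0.40). Nf1 lies in a stretch of chromosome 11 that was less dense outside accessible regions in clusters 5 and 14, and its ratio minus that of neighbouring genes was −0.15. Not every member of this and the other lists that lies in such a stretch is marked in the text. The ratios of others may therefore follow density in the same way. Of the list members named, Il1rap, Aldh1l2, Dnmt1, Kdm1a, Rrm2, Rsad2 and Mbp went the other way with equal cluster weights, and Aldh1l1, Slc2a3 and Vldlr at promoters alone.

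**Figure D2:**
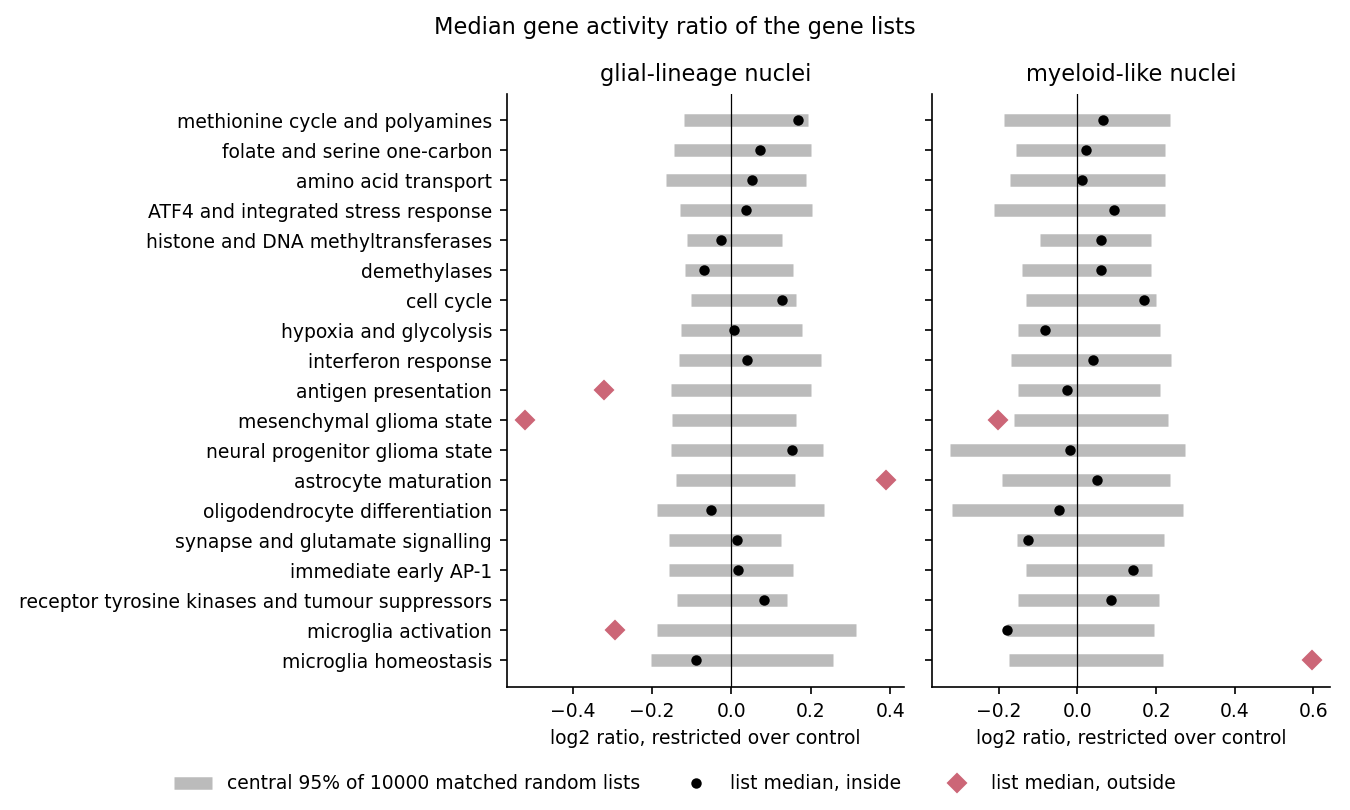
Median log2 ratio of gene activity, restricted over control, of each of 19 gene lists (dots) in glial-lineage and in myeloid-like nuclei, over the central 95% of 10000 random lists matched on size and mean activity (grey bars). In glial-lineage nuclei the mesenchymal (−0.52), antigen presentation (−0.32), microglia activation (−0.29) and astrocyte maturation (0.39) lists lie outside, and in myeloid-like nuclei the microglia homeostasis (0.60) and mesenchymal (−0.20) lists.

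The same comparison in myeloid-like nuclei, 1080 in control and 202 under restriction, asks how the immune cells of the tumour differed. Genes of homeostatic microglia were more accessible in the restricted library, with a median of 0.60 (percentile 100) and 12 of 14 members above 0. The Fc receptor-like gene Fcrls was at 1.59 (0.95 to 2.18) and the lectin Siglech at 0.90 (0.31 to 1.43). Within cluster 9, which holds nuclei of both libraries, the median of this list was 0.79. Mesenchymal state genes were lower, at −0.20 (percentile 0.790) with 12 of 18 members below 0, and included Cd44, the hyaluronan receptor, at −1.17 (−1.59 to −0.80), and the intermediate filament gene Vim at −0.77. Microglia activation genes lay just inside the central range, at −0.18 (percentile 2.57), with the protease inhibitor Cst7 at −1.01 (−1.92 to −0.30) and Apoe at −0.79 (−1.54 to −0.18), but at 0.06 within cluster 9. The mesenchymal list lay inside the central range in nuclei of at least 5000 fragments, at −0.11, and Apoe was at 0.22 at its promoter.

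By the same rule of size, the genes with the highest ratios in myeloid-like nuclei were Cwc22 (2.22, 2.04 to 2.40), the organic anion transporter Slco5a1 (2.13, 1.71 to 2.54), the NKG2D ligand gene H60b (2.08, 1.49 to 2.64), the glyoxalase Glo1 (1.98, 1.63 to 2.31) and the incretin receptor Glp1r (1.78, 1.09 to 2.41). Cwc22, Glo1 and Glp1r lie in the stretches that were higher in all 4 large classes. The lowest ratios were those of the peptidase Cpq (−1.83, −2.67 to −1.18), the GATA-type repressor Trps1 (−1.59, −1.98 to −1.24), the membrane mucin Pdpn (−1.50, −2.12 to −0.99), the monocyte-attracting chemokine Ccl7 (−1.47, −2.62 to −0.63) and the inhibitory receptor Lilrb4a (−1.45, −2.68 to −0.57).

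The remaining lists also lay inside the central range in myeloid-like nuclei. Methionine cycle genes were at 0.06 (percentile 60.5), with Ahcy, which removes S-adenosylhomocysteine, at 1.14 (0.54 to 1.68) and the salvage enzyme Apip at 0.57 (0.13 to 0.97). Folate genes were at 0.02, amino acid transport at 0.01, the ATF4 list at 0.09, methyltransferases at 0.06 and demethylases at 0.06. In those lists the members with the largest ratios were Mthfs (−0.71) and Slc19a1 (0.54), Slc38a1 (−0.58) and Slc7a11 (−0.56), Cebpg (0.70) and Chac1 (0.66), Dot1l (−0.69) and Kmt2a (0.63), and Kdm4b (0.46) and Kdm7a (−0.44). Antigen presentation genes were at −0.03 (percentile 25.9), with the class II activator Ciita at −0.56 (−0.97 to −0.19; 0.01 within cluster 9) and Cd74 at 0.49 (0.31 to 0.67). Interferon response genes were at 0.04 (Cxcl10 −0.52, Ifih1 −0.51), hypoxia genes at −0.08 (Pgk1 −0.50, Adm −0.35), cell cycle genes at 0.17 (Ccnb2 −0.80, Ccne2 0.67) and AP-1 genes at 0.14, the last with Jun at 0.89 (0.65 to 1.11) and Fosl2 at −0.66. The astrocyte list had a median of 0.05 (Hes1 −0.81, Apoe −0.79), the oligodendrocyte list −0.05 (Myrf −0.52, Cnp 0.25), the neural progenitor list −0.02 (Dll1 1.03, Sox4 0.90), the synapse list −0.13 (Grin2a 1.11) and the kinase list 0.09 (Cdkn1a −0.73, Cdkn2a 0.70). The intervals of Slc19a1, Chac1, Kdm7a, Cxcl10, Ifih1, Pgk1, Adm, Ccnb2, Ccne2, Myrf and Cnp hold 0. Mthfs and Dll1 went the other way within cluster 9, Slc38a1 at its promoter, and Cdkn2a at its promoter and with nuclei thinned to equal depth.

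Where fragments lay in the genome was compared next, since S-adenosylmethionine is the methyl donor for the histone marks of silent chromatin. Promoters, within 1 kb of a TSS, held 22.7% of the fragments of the restricted library and 21.0% of those of the control library. Gene bodies held 44.3% and 45.5%, and places more than 100 kb from any gene 8.77% and 7.98%. The promoter share was higher under restriction in each of 5 classes, by least in oligodendrocyte-like nuclei, at 22.6% against 22.1%, and by most in endothelial-like nuclei, at 28.2% against 24.7%. The difference over all nuclei, 1.69 points, was 3.44 points among fragments shorter than a nucleosome. The median TSS enrichment of the libraries, 18.5 and 16.3, differed the same way, so a difference in library quality that raises this share in every class stays open. Far intergenic fragments differed by class instead, at 10.3% against 9.13% in glial-lineage nuclei but 6.67% against 7.04% in myeloid-like and 6.01% against 7.02% in endothelial-like nuclei.

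Of the gene families that lie in silent chromatin in many cells, Hox genes, the homeobox genes of the body axis, stood apart in glial-lineage nuclei, with a median log2 ratio of 0.58 (percentile 100) and 30 of 39 members above 0. Hoxa3 is a leading gene of cluster 14. Hox genes lie in groups along chromosomes, so members may have shifted together, for which the random lists make no allowance. Zfp genes, mostly zinc finger repressors, were at 0.14 (percentile 100). Clustered protocadherins were at −0.07 (percentile 9.39), within their random lists, but at −0.60 (percentile 0) at promoters alone. In myeloid-like nuclei the medians were 0.19 for Hox genes (percentile 96.3) and 0.10 for Zfp genes (percentile 99.8; 53.3 at promoters alone). Olfactory and vomeronasal receptor genes held few fragments, so that the intervals of 1028 of 1053 and 246 of 253 of them held 0 in glial-lineage nuclei, as did those of 55 of 56 protocadherins in myeloid-like nuclei. These medians largely follow the prior count and are not given.

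The share of glial-lineage fragments in each 10 Mb window, relative to myeloid-like nuclei of the same library, was taken to look for copy number differences. Of 248 windows, 82 in the restricted and 48 in the control library lay more than 25% above or 20% below the myeloid share. The ratios of the libraries were as far apart as that in 11 windows. On chromosome 11, which carries Trp53 and Nf1, the ratio to myeloid-like nuclei from 70 to 80 Mb was 0.587 under restriction and 0.810 in control, and from 80 to 90 Mb 0.706 and 0.899. On chromosome 12 from 20 to 30 Mb it was 2.11 and 1.34, on chromosome 14 from 110 to 120 Mb 2.22 and 1.66, and on chromosome 5 from 40 to 50 Mb 1.70 and 1.21. Chromosome Y held 0.0177% of fragments under restriction and 0.0231% in control.

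Single clusters were then compared, a step chosen after these windows were seen, by their fragments outside accessible regions relative to the control library's clusters 2 and 4. These 2 clusters are oligodendrocyte precursor-like, a class in which tumour nuclei were expected, so the reference may carry copy changes of its own. The ratios are therefore not shown to be copies relative to normal cells. In the restricted library's cluster 5, the stretch of chromosome 18 from 26 to 32 Mb, which holds Lims2, Gpr17, Syt4 and Pik3c3, was at 4.65 (4.47 to 4.84), and chromosome 12 from 26 to 31 Mb, which holds Adi1 and Rsad2, at 2.15 (2.07 to 2.23). The control library's nuclei of cluster 5 were at 0.919 and 1.57. Syt4 itself had 1 of the lowest gene activity ratios over all glial-lineage nuclei, −1.62, so the higher density was not shown to hold at that gene. From Trp53 (chromosome 11, 69580348 to 69591873) to Nf1 (79339590 to 79581609), the ratio was 0.694 (0.675 to 0.714) in cluster 5, 0.615 (0.596 to 0.635) in cluster 14 and 0.499 (0.467 to 0.532) in the unnamed cluster 19, all of the restricted library. The restricted library's unnamed cluster 8 was at 0.795 (0.757 to 0.835) there, against 0.980 in control. Astrocyte-like cluster 11 of the restricted library was at 0.999 and oligodendrocyte-like cluster 3 at 1.17 in the restricted and 1.22 in the control library. Cluster 11, with 181 nuclei of the restricted library, counts among the glial-lineage nuclei, and cluster 19 does not. Within 1 Mb of Egfr, cluster 14 was at 2.26 (2.095 to 2.442). This ratio also differs between classes of nuclei, since the astrocyte-like clusters 11 of the restricted and 17 of the control library were at 1.62 (1.46 to 1.80) and 1.52 (1.35 to 1.70), and oligodendrocyte-like cluster 3 at 0.604 and 0.644 in the restricted and control library.

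**Figure D3:**
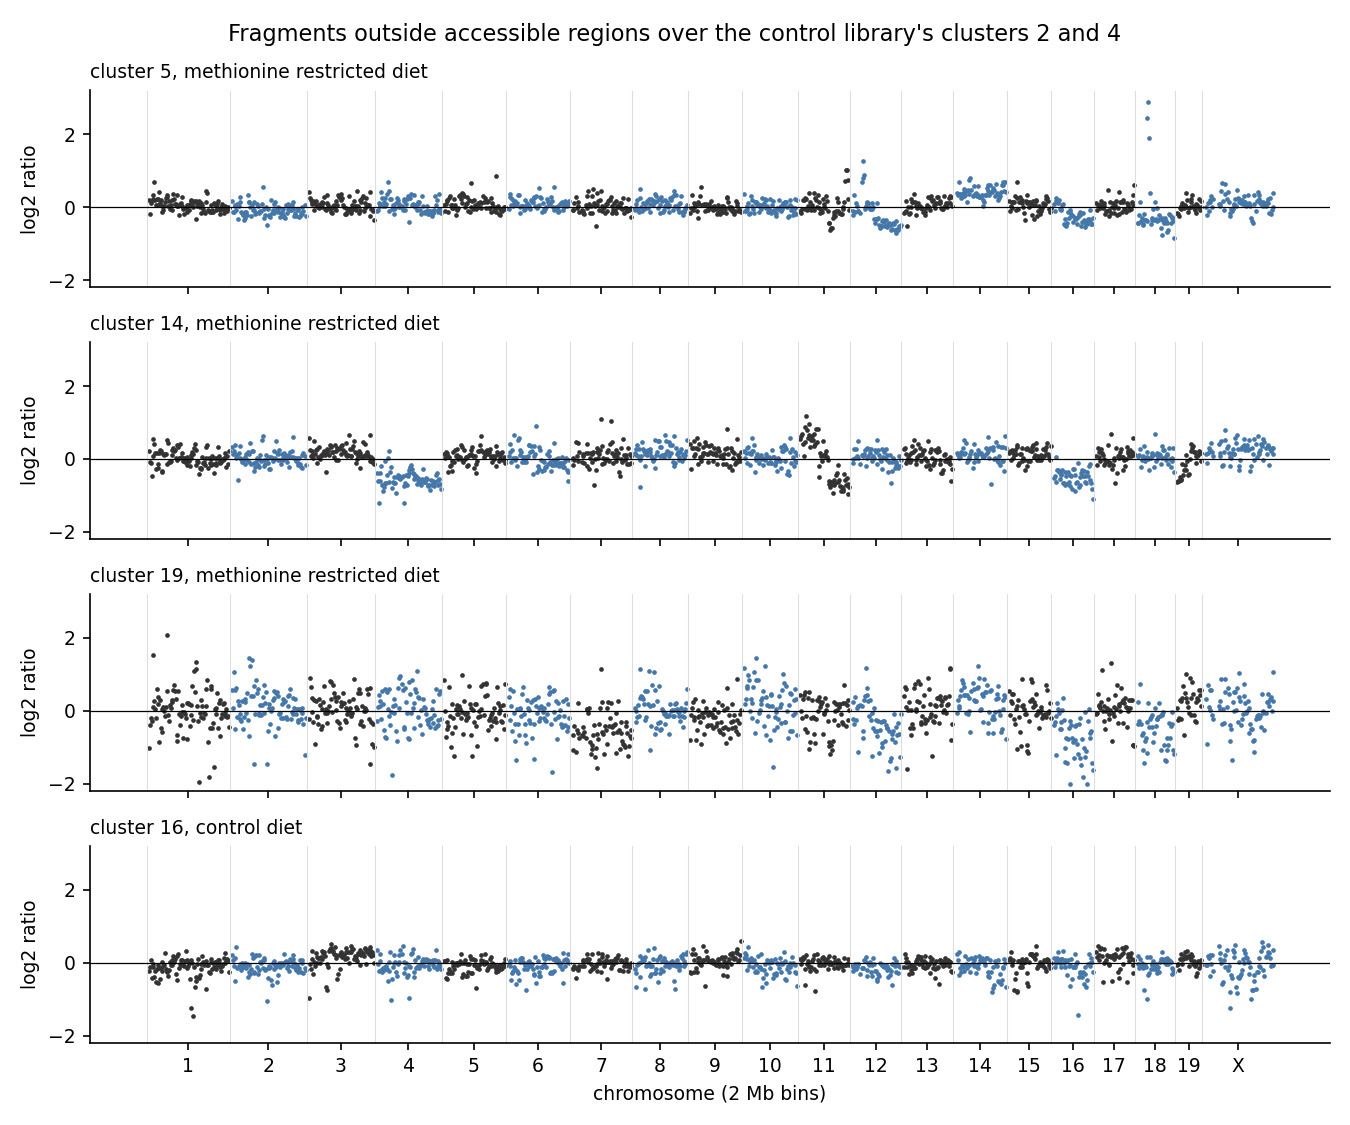
Log2 ratio of fragments outside accessible regions in 2 Mb bins along the genome (x axis, chromosomes in order) for clusters 5, 14 and 19 of the restricted library and cluster 16 of the control library, each over the control library's clusters 2 and 4. Cluster 5 stands at 4.65-fold from 26 to 32 Mb of chromosome 18.

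**Figure D4:**
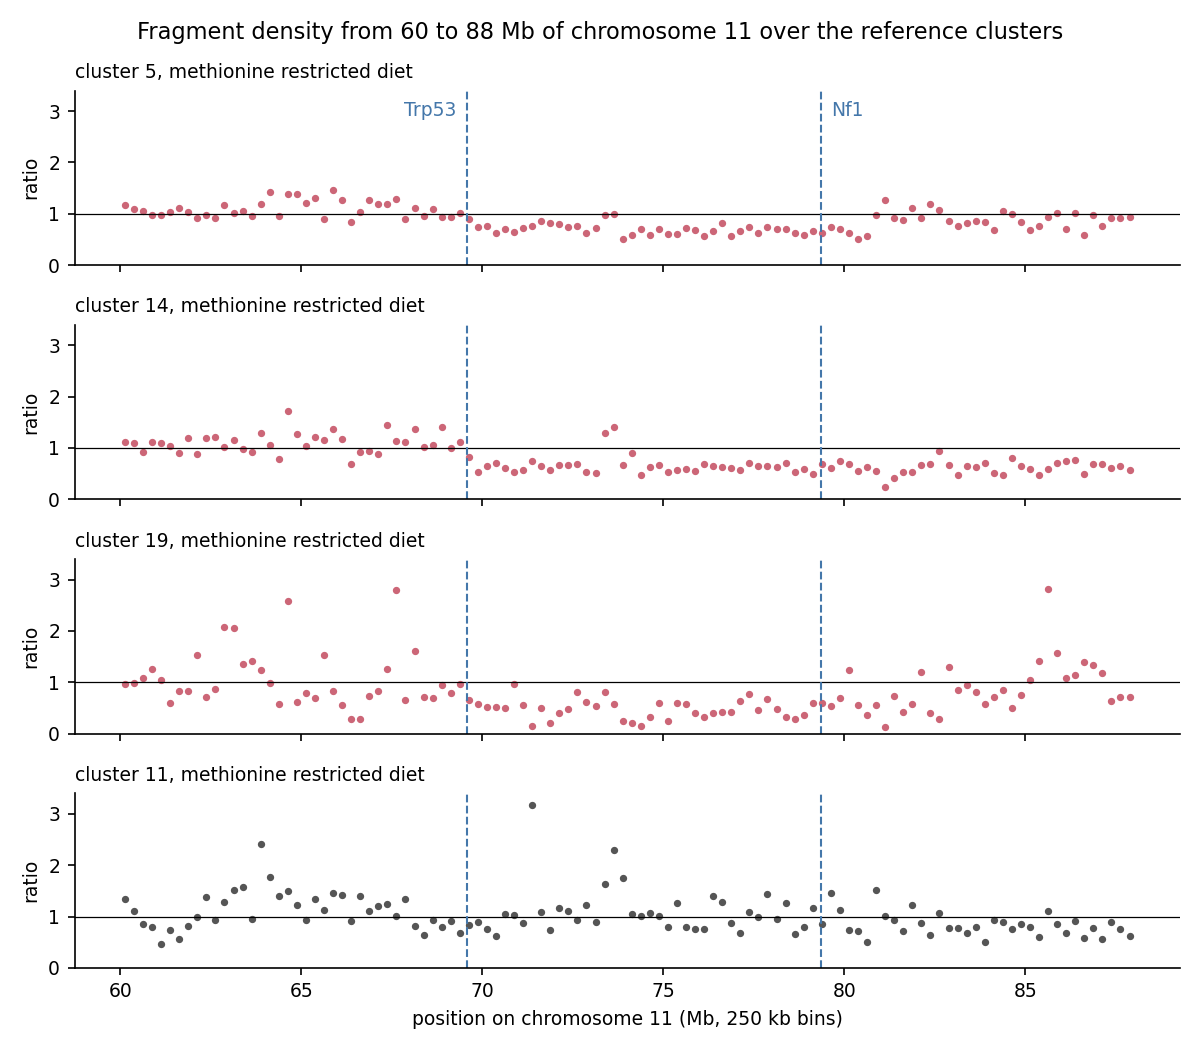
Ratio of fragments outside accessible regions to the control library's clusters 2 and 4 in 250 kb bins (x axis, position on chromosome 11 in Mb) for clusters 5, 14, 19 and 11 of the restricted library, with dashed lines at Trp53 and Nf1. From Trp53 to Nf1, clusters 5, 14 and 19 lie at 0.694, 0.615 and 0.499 and cluster 11 at 0.999.

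Accessible regions of glial-lineage nuclei were compared last, to find single regulatory sites that differed. The 69972 regions covered 42.1 Mb, 15.7% of them at promoters, and held 37.2% of fragment ends in control and 35.6% under restriction. Distal regions differed more between the libraries, with a standard deviation of log2 ratios of 1.19, than promoter regions, with 0.465. The region with the highest ratio lay within Lims2 (chromosome 18, 31953501 to 31954000), at 3.00 (2.80 to 3.21), and another within Pik3c3, a lipid kinase of autophagy, in the same stretch (30272501 to 30273000), at 2.39. The promoter of Sox1 (chromosome 8, 12395001 to 12396000) was at 2.64, a site 12.2 kb from the homeobox gene Dbx2 (chromosome 15, 95667001 to 95667500) at 2.54, and one 36.7 kb from Ralgapa2 (chromosome 2, 146549001 to 146550000) at 2.53.

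The region with the lowest ratio lay 48.0 kb from Gm11232 (chromosome 4, 71806001 to 71806500), at −4.35 (−5.57 to −3.49). A site 19.7 kb from the small GTPase gene Arl4d (chromosome 11, 101687501 to 101688500) was at −3.69, and one within Siva1, a gene of apoptosis (chromosome 12, 112648001 to 112648500), at −3.09. A site whose nearest gene, 167 kb away, was the cell cycle inhibitor Cdkn2b (chromosome 4, 89478501 to 89479500) was at −3.17, and one 76.9 kb from the pseudokinase gene Trib1 (chromosome 15, 59734001 to 59735000) at −3.02. Subtracting the median of regions within 5 Mb left the sign of all 10 of these regions the same, but at ratios of this size it could hardly do otherwise. It moved the Lims2 region only from 3.00 to 2.93. Yet fragments outside accessible regions over Gpr17 and most of Lims2 were 4.22-fold (3.71 to 4.82) denser in glial-lineage nuclei of the restricted library. The stretch counted, 31922293 to 31949890, ends short of the named region within Lims2. The subtraction therefore does not check these regions for local copy number.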

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

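The comparison given here was chosen only after the result was seen. Barcodes with more than 100000 fragments lie above the limit for nuclei and enter no comparison, yet 35 of them held 56.8% (56.8 to 56.9) of the nuclear fragments of the restricted library, more than in control, where 25 held 23.7%. Their median TSS enrichment was 1.24 and 1.17, against 18.5 and 16.3 in the nuclei kept, and their median share of mitochondrial fragments was 0.00855% and 0.0174%, against 0.230% and 0.173%.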

How the results depend on the processing

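Tests by cluster (without clusters 11 and 14, without the neural progenitor or glioma-like cluster, precursor-like clusters only, cluster 9 only, without cluster 12) and the leading-gene minimums were chosen only after the result was seen. No paired analysis was possible because each diet had 1 library, which also rules out leaving a library out. The motif alternatives were not run for want of a genome sequence. Equal cluster weights rested on clusters 5 and 11 alone, with few control nuclei, and for the values given here the cause was not tested.

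Shares are given as points of difference, restricted minus control. The glial-lineage difference of 10.6 was −11.7 with leading genes at 10 per 1000000, 21.5 with at least 1000 fragments and TSS enrichment of 3, −0.626 at resolution 0.5, −11.0 at resolution 2 and −0.438 with thinned nuclei. The oligodendrocyte precursor-like difference of −9.29 was 10.02 with at least 1000 fragments and −20.3 at resolution 2. The astrocyte-like difference of 9.29 was −2.38 with leading genes at 10, 7.37 with at least 5000 fragments and 11.5 with at least 1000. The lymphocyte-like difference of −5.78 was −4.21 and −8.69 at those minimums.

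In glial-lineage nuclei the standard deviation of gene log2 ratios, 0.318, was 0.397 at promoters, 0.332 with at least 5000 fragments, 0.385 thinned, 0.290 at 50 per 1000000, 0.297 minus neighbouring genes, 0.603 with equal weights, 0.344 without the progenitor cluster, 0.357 without clusters 11 and 14 and 0.371 in precursor-like clusters. Lists outside the central range numbered 4, but 1 with equal weights and 2 in precursor-like clusters. At promoters Aldh1l1 was 0.62, Slc2a3 0.64 and Vldlr −0.051. With equal weights Aldh1l2 was 1.10, Cdsn 0.30, Dnmt1 0.035, Il1rap 0.97, Kdm1a 0.52, Mbp 0.40, Rrm2 −0.56, Rsad2 −0.020, Sox1 −0.26, Zic1 −0.99 and Zic4 −1.24. Aqp4 was −0.45 without clusters 11 and 14 and −0.44 in precursor-like clusters, and the astrocyte maturation list −0.018 without clusters 11 and 14. Of 631 values of 55 named or list-leading genes under alternatives, 610 kept the sign, and of 227 values of the 19 list medians 187 did, with 5 lists keeping it in all.

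In myeloid-like nuclei that standard deviation, 0.363, was 0.483 at promoters, 0.441 with at least 5000 fragments, 0.474 thinned, 0.317 at 50 per 1000000, 0.399 without cluster 12 and 0.654 in cluster 9. Lists outside numbered 2, but 1 with at least 5000 fragments, 5 thinned and 4 in cluster 9. Apoe was 0.22 at its promoter, Slc38a1 0.013 at its promoter and Cdkn2a −0.086 at its promoter and −0.35 thinned. Within cluster 9 Ciita was 0.00749, Dll1 −0.59 and Mthfs 0.27. Of 388 values of 46 genes, 379 kept the sign, and of 170 list medians 136 did, with 8 of 19 lists keeping it in all.

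The standard deviation over regions, 1.05, was 1.04 at 8 times the local mean, 1.04 minus neighbouring regions, 0.944 with at least 5000 fragments and 0.890 in precursor-like clusters. The promoter share difference of 1.69 points was 1.14 in glial-lineage nuclei and 3.44 in fragments shorter than a nucleosome. Windows with the libraries apart numbered 11, 11 and 10. The 202 myeloid-like and 14 lymphocyte-like nuclei of the restricted library limit what depth can show there.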

Other observations

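The comparisons of oligodendrocyte-like and endothelial-like nuclei, and all tests here except that at equal fragments per nucleus, were chosen only after the result was seen. Oligodendrocyte-like nuclei fell in cluster 3 in both libraries, 399 in control and 180 under restriction. Some genes of the response to interferon were less accessible there in the restricted library. The lowest ratios were those of Gbp4, a guanylate-binding GTPase (log2 −3.14, −5.21 to −1.89), the interferon-inducible GTPase gene Gm4951 (−2.66), the nucleic acid sensor Zbp1 (−2.63), Gbp5 (−2.14) and Cd74 (−2.06, −3.51 to −1.03). Antigen presentation genes had a median of −0.80 (percentile 0; 13 of 14 members below 0), and interferon response genes one of −0.59 (percentile 0.005; 16 of 19), with the RNA sensor Ddx58 at −1.29. The intervals of 17 of the 19 interferon response genes held 0. Immediate early AP-1 genes were at −0.31 (percentile 0.0300), among them the phosphatase Dusp1 (−0.80), and mesenchymal genes at −0.26 (percentile 0.970). Neural progenitor state genes were at 0.44 (percentile 97.9), with Insm1 at 0.97 and intervals that held 0 in 15 of 18 members. Oligodendrocyte differentiation genes were at 0.01. The highest ratios were those of the adhesion molecule Cntn3 (2.89, 2.32 to 3.53), Dnah8 (2.19), Cwc22 (2.11), Glo1 (1.89) and Mapk11 (1.74).

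Endothelial-like nuclei came mostly from cluster 6 in control (312 nuclei in the class) and cluster 10 under restriction (210 nuclei). Genes of the mesenchymal state were lower there, with a median of −0.36 (percentile 0.0700; 14 of 18 members below 0), among them S100a11 at −1.58. Antigen presentation genes were at −0.34 (percentile 0.280; 13 of 14 below 0), with Cd74 at −1.64 and H2-D1 at −0.85, and synapse genes at −0.31 (percentile 0.370). Macrophage and lymphocyte markers were lower in these nuclei too, with a summed ratio of 0.795 (0.700 to 0.902) against 0.765 (0.695 to 0.841) for antigen presentation genes, so fewer stray fragments of immune nuclei stay open as a reason in this class. The lowest ratios were those of Ccdc192 (−3.62, −4.27 to −3.07), Rnf183 (−2.64), Oit1 (−2.61), the matrix protein Emilin2 (−2.48) and Oaf (−2.38). The highest, beside Cwc22 (2.49) and Glo1 (2.17), were Tecrl (2.26), Pla2g2c (1.99) and Lao1 (1.88).

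Cwc22 and the stretch from Glo1 to Glp1r (chromosome 17, 30592861 to 30936510) were higher in the restricted library in all 4 large classes, by 4.12-fold in glial-lineage, 4.29-fold in myeloid-like, 4.12-fold in oligodendrocyte-like and 5.65-fold in endothelial-like nuclei for Cwc22, and 9 of 8176 bins of 100 kb were at least 1.5-fold higher in all 4, 3 from 77800001 to 78100000 on chromosome 2 and 6 from 30400001 to 31000000 on chromosome 17, which reach beyond these genes and into Btbd9. Lower by as much in all 4 were 3 bins, on chromosomes 5, 12 and 16. More open chromatin as the whole cause is argued against by the fragments outside accessible regions, which were 3.67-fold denser from Glo1 to Glp1r in glial-lineage nuclei. A candidate explanation is more germline copies in the animal of the restricted library. Outside accessible regions the lowest ratio over both places and the 4 classes was 3.31. These regions were called in glial-lineage nuclei, so the fragments of the other classes outside them can still include open chromatin. By the same fragments the stretch from the start of Btbd9 to Glp1r was at 2.27 to 2.68, and flanks within 2 Mb, taken before Btbd9 and from 100 kb off Cwc22 and Glp1r, were at 0.812 to 1.19. Both places are known to vary in copy number among laboratory mice. The animals may then differ in genetic background as well as in diet, which these libraries do not separate.

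Clusters 5, 14 and 19 of the restricted library had fewer fragments from Trp53 towards Nf1. The chromatin of the cell type is argued against in cluster 5 by the control library's nuclei of cluster 5, at 0.896 (0.837 to 0.960) against 0.694 (0.675 to 0.714). Clusters 14 and 19 had 7 and 3 control nuclei, too few for that comparison. A candidate explanation is a loss of copies that begins at Trp53, a tumour suppressor, since the most likely step lay 0.00813 Mb from the gene in all 3 clusters, in bins of 50 kb. It was not shown to end at Nf1, as the step back lay at least 1.17 Mb beyond that gene in clusters 5 and 19, and cluster 14 was at 0.618 from Nf1 to the end of the chromosome. Among 8846 places, 2 more than 5 Mb from Trp53 had a shared step at least as strong. The strongest shared fall lay on chromosome 4 at 31750000, where the weakest of the 3 clusters was at log2 −0.590, against −0.481 at Trp53. Whether the diet bears on such losses was not tested.

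The lower antigen presentation genes of oligodendrocyte-like nuclei had a summed ratio of 0.578 (0.516 to 0.647). Fewer stray fragments of immune nuclei are argued against by macrophage and lymphocyte markers in the same nuclei, at 1.01 (0.888 to 1.15), and fewer fragments per nucleus by the ratio at 2000 fragments in each, 0.612 (0.512 to 0.729). A strain variant that keeps these fragments from aligning stays open. The same genes had a ratio of 1.10 (1.03 to 1.17) in myeloid-like nuclei. Those nuclei came mostly from different clusters in each library, so a difference in their makeup could mask a variant. In glial-lineage and endothelial-like nuclei the same genes were lower under restriction too, at 0.785 (0.748 to 0.823) and 0.765 (0.695 to 0.841). The diet cannot be told apart from other differences between the animals with 1 library per diet.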
